A study of Mus musculus with 48 samples.

How the data were processed

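Gene expression was measured on 48 one-colour Affymetrix arrays, each hybridized with biotin-labelled total RNA from white blood cells of the spleen of C57BL/6 mice aged 8 to 10 weeks. The 16 groups combine sex, gonadectomy (intact or gonadectomized, gdx below) and the day of *Plasmodium chabaudi* AS infection (day 0 before infection, and days 3, 7 and 14). Each group had 3 arrays, and each array carried a pool of 3 mice. The deposited values are in the unit intensity, as signals on a linear scale that the labels credit to GCOS 1.2 and MAS5. The version of MAS5 is not given in the sources used here, and neither are the scaling target and the present or absent calls. The mean signal of every array with 2% trimmed from each end lay between 500.1 and 500.2, so all arrays had been scaled by the authors to a common target. No further normalization was applied in the primary analysis.

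The arrays held 22690 probe sets, of which 64 were controls and were left out. Gene symbols came from the platform annotation, where 20380 probe sets carried 1 symbol, 691 carried several and 1555 carried none; only those with 1 symbol were used for genes. Symbols were matched by gene number to a RefSeq gene table used for names only, with 29 unmatched and 0 changed. A probe set was kept when its signal was above the median of its own array in at least 6 of the 48 arrays, which 13467 probe sets were. Each gene was then represented by its probe set with the highest mean, which gave 8121 tested genes; 2784 of them had more than 1 probe set past the filter. Signals were floored at the 20th percentile of all values (41.4) and taken to log2. Where a share of 0.25 or more of the arrays on a side of a comparison sat at the floor, the change or fold is given as a lower bound.

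Computation used R 4.3.3 with limma 3.58.1. A linear model with 1 mean per group (32 residual degrees of freedom) was fitted by lmFit, and eBayes with an intensity trend moderated the variances. Every p was 2-sided and adjusted by the Benjamini-Hochberg method over all tested genes within a comparison, with a threshold of 0.05. Infection was compared at each day with day 0 in each of the 4 sets (intact females, intact males, gdx females, gdx males) and as the mean of the 4 sets. Sex was compared as female minus male within intact and within gdx mice, at each day and as the mean of 4 days. Gonadectomy was compared as gdx minus intact within each sex as the mean of 4 days. The interaction of sex and gonadectomy was the sex difference in intact mice minus that in gdx mice. Interactions with infection were moderated F tests over the 3 infected days.

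Fixed lists of genes (24 in number) were set by name, and the 22 with at least 4 tested members were tested with camera at a preset correlation of 0.01, adjusted over all lists and comparisons of the same question. Camera with a correlation estimated from the residuals and fry were run beside it. The lists of germinal centre and of Y-linked genes had 3 tested members each and are given as genes only. For the lists described, the text gives how many members passed the threshold over all genes, and beside it the count adjusted over the list alone where it differed. Genes are named in the text by a fixed rule. It takes the 8 largest rises and falls for infection with the same sign in all 4 sets and both means above the floor, the 6 largest each way for sex, gonadectomy and their interaction with the sex-linked lists set aside, the 4 largest each way for sex at 1 day, the 10 smallest adjusted p for each F test, and the 4 largest changes in each list. A set of gene names was also fixed; of these Ifng, Il10, Tnf, Cxcl9, Xist and Eif2s3y were tested, Il12b and Esr1 were too dim, and the other 3 were not analysed here. Other probe sets were checked for the genes with the largest changes for infection, sex, gonadectomy and sex by gonadectomy. For 0 of these did another probe set pass the threshold in the opposite direction. Other probe sets that had the opposite sign without passing are given beside the gene. Genes named by an F test, a list or the fixed names were not checked in this way.

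The comparisons, the tests, the lists, the naming rule, the fixed gene names and all alternatives but the last were chosen before the data were examined. The alternatives were quantile normalization, a floor at the 5th percentile (8.3), no filter on dim probe sets, every probe set as its own feature, the replicate number as a block, only the arrays of the groups compared, eBayes without the intensity trend, camera with an estimated correlation, fry, and leaving out each array in turn. The last, leaving out 1 array with signals of both sexes, was added after the data were seen. Replicate numbers were checked for pairing: residuals of arrays with the same number had a mean correlation of 0.073 over 360 pairs, against −0.036 for other numbers, and 38 of 48 arrays correlated best with their own number. On the second residual component (9.94%) all 16 replicate 1 arrays lay on one side and 29 of the 32 others on the opposite side. Whether the numbers mark a batch or any pairing is not given in the sources used here, and they entered only as an alternative.

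The pipeline was tested on simulated data in which 200 genes were changed. For the day 7 mean it recovered 79.1%, 97.0% and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, and for day 7 in intact females alone 26.9%, 71.6% and 100%. The same shares were 74.6%, 95.5% and 100% for sex in gdx mice as the mean of 4 days, 16.4%, 67.2% and 90.9% for sex in gdx mice at day 0, 65.7%, 77.6% and 98.5% for sex by gonadectomy, and 2.99%, 28.4% and 84.9% for sex by infection in intact mice. For sex by infection the fold was that of the day 3 difference, and the simulated differences at days 7 and 14 were smaller. False calls in the 6 simulations numbered 10, 7, 6, 4, 8 and 6. Of the simulated lists of 15 members, 20 of 20 shifted by 0.5 on the log2 scale were called and 0 of 20 unshifted ones. The simulated genes varied independently, so false calls of lists whose members vary together were not measured. When the sexes were relabelled in the real arrays, up to 36 list calls of sex were made. The number of arrays limits the precision. The p-values measure only the spread between these samples.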

Results

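The data were 48 arrays of splenic white blood cell RNA, with 3 arrays in each of 16 groups and 3 mice pooled for each array, or 144 mice in all. All arrays were scaled to the same trimmed mean, and within-group correlations over genes lay between 0.906 and 0.975. The first principal component held 46.6% of the variance and the second 9.85%. On the first, days 0 and 3 overlapped, and days 7 and 14 followed apart from them. Changes below are log2 differences ± standard error, with 12 arrays against 12 for means over sets or days and 3 against 3 within a set or at 1 day. The median change of all genes was −0.14 at day 7 and −0.13 at day 14.

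**Figure D1:**
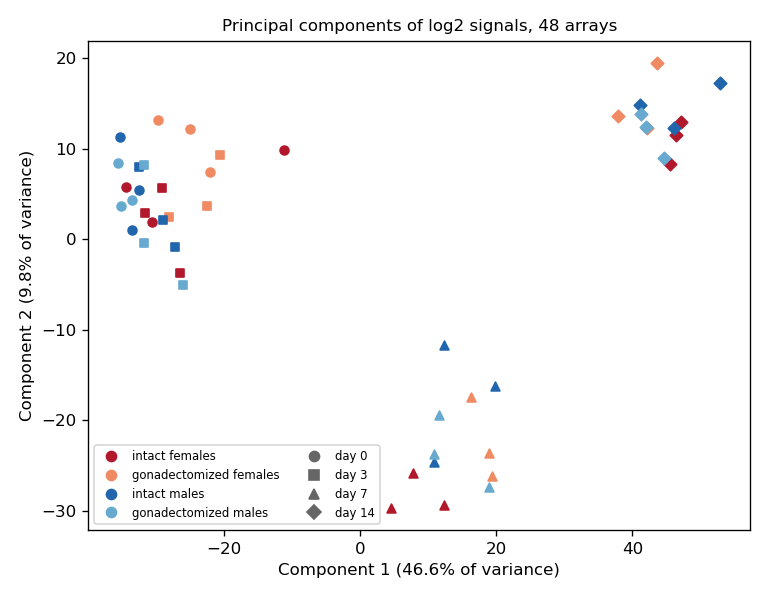
Scores of the 48 arrays on the first 2 principal components, which held 46.6% and 9.85% of the variance. The intact female day 0 replicate 1 array scored −11.2 on the first component, and the other arrays of its group −34.4 and −30.6.

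The first question was how splenic leukocytes responded to infection, starting with day 3. Interferon-induced genes rose first. The chemokine gene Cxcl9 rose by 2.51 ± 0.27 (5.71-fold, adjusted p = 8.14e-09), and the guanylate-binding protein genes Gbp2 (2.33 ± 0.17), Gbp6 (2.26 ± 0.15, adjusted p = 3.52e-14) and Gbp7 (1.71 ± 0.16) rose with it. So did the immunity-related GTPase genes Iigp1 (1.79 ± 0.13) and Igtp (1.55 ± 0.12), the chemokine gene Cxcl10 (1.76 ± 0.22) and Zbp1 (1.60 ± 0.11), a sensor of nucleic acids. The largest falls were smaller: Hic1, a transcriptional repressor, by 1.08 ± 0.27 (adjusted p = 0.0146), the amino acid transporter gene Slc7a5 by at least 0.82 and Ccdc186 by 0.72 ± 0.20. The haem synthesis gene Alas2 fell by 0.66 ± 0.18 (adjusted p = 0.0432), Bpgm, an enzyme of red cells, by 0.57 ± 0.16, and Ccpg1, Tent5c and the adhesion molecule gene Vcam1 by 0.56 each. Each of these 8 falls lost its call under at least 1 alternative, while Cxcl9 and the other 7 rises kept theirs under all of them. The other probe sets of Bpgm and Vcam1 were also lower but did not pass.

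Of the 22 tested interferon-inducible genes, 21 rose at day 3 (median 1.19, adjusted p = 5.00e-77, and 3.49e-05 with an estimated correlation), among them Oasl2 (1.34), Ifit3 (1.29) and Irgm1 (1.23). Only Rsad2 did not pass (0.21 ± 0.14, adjusted p = 0.591). The list median was 1.02 in intact females, 1.33 in intact males, 1.06 in gdx females and 1.24 in gdx males. In the list of the interferon-gamma axis 6 of 17 rose, or 7 adjusted over the list alone (median 0.20, adjusted p = 0.00256 with an estimated correlation). Il12rb1 rose by 1.41 ± 0.22, Irf1 by 1.21 ± 0.12, Socs1 by 1.15 ± 0.19 and Ifng itself by 0.52 ± 0.13 (adjusted p = 0.0185), which passed in no single set. The cytokine gene Tnf did not pass (−0.03 ± 0.35, adjusted p = 0.986). Among natural killer genes Gzmb (0.74 ± 0.12) and Xcl1 (0.73 ± 0.16) rose, and so did Bst2 (0.67 ± 0.13) of the dendritic list and the checkpoint ligand gene Cd274 (0.88 ± 0.08) of the regulatory list. In the immediate early and heat shock list 4 genes fell, or 6 adjusted over the list alone with 1 rising. They were Hspa1b (−0.90 ± 0.23), Hspa1a (−0.78 ± 0.22), Dnajb1 (−0.47 ± 0.09) and Btg2 (−0.37 ± 0.09). The list call, with a median of −0.13, was lost at adjusted p = 0.0671 with an estimated correlation.

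In total 205 genes passed at day 3, 152 higher and 53 lower, with 27 and 3 changed more than 2-fold. Of the 205, 194 had the same sign in all 4 sets. Single sets gave 18 genes in intact females, 30 in intact males, 21 in gdx females and 32 in gdx males, of which 10 were shared by all 4. The count in intact females was 3 without its day 3 replicate 3 array, whose interferon-inducible genes averaged 11.4 against 10.2 in the group's other arrays, and 45 without its day 0 replicate 2. The count in intact males was 9 without day 3 replicate 2 and 48 without day 3 replicate 3, that in gdx females 10 without day 3 replicate 3, and that in gdx males 18 without day 3 replicate 1.

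**Figure D2:**
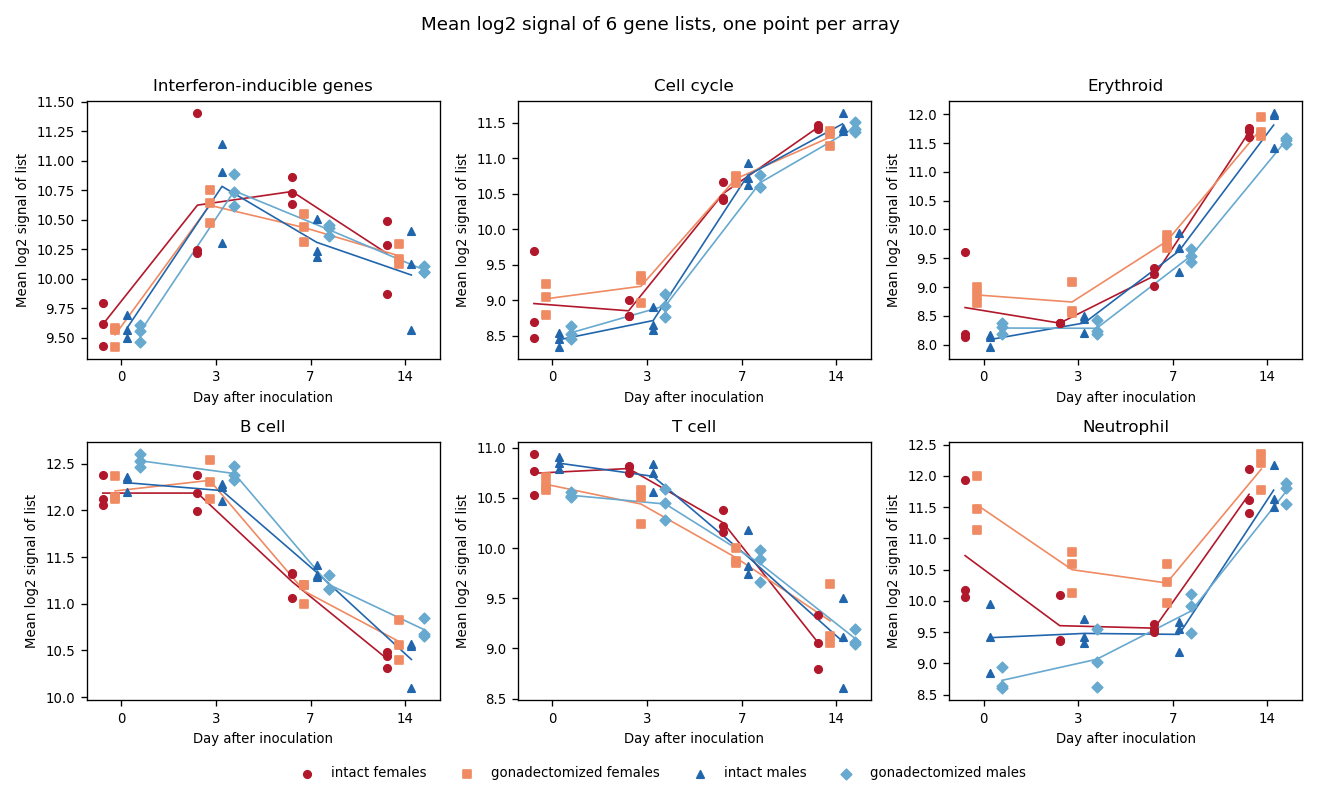
Mean log2 signal of 6 gene lists by array and day. The interferon-inducible list rose by a median of 1.19 at day 3, cell cycle genes by 1.60 at day 7 and erythroid genes by 3.44 at day 14.

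At day 7 the complement factor gene Cfb, at the floor in a share of 0.917 of the day 0 arrays, rose by at least 4.62 (24.6-fold). Cxcl9 rose by 4.41 ± 0.27 (21.2-fold), the cytotoxic protease gene Gzmb by 4.36 ± 0.12 (20.6-fold) and the acute phase gene Saa3 by 4.22 ± 0.18 (18.6-fold). The antibody constant region gene Ighg3 rose by 3.74 ± 0.19, the mitotic kinase genes Cdk1 by 3.68 ± 0.28 and Bub1b by at least 3.35, and the metallothionein gene Mt2 by 3.31 ± 0.12. Genes of mature B cells and their receptors fell: Fcer2a by 2.67 ± 0.14 (6.37-fold), the complement receptor gene Cr2 by 2.50 ± 0.09 (5.65-fold) and the complement regulator gene Cd55 by 2.22 ± 0.12. Falls of the same order were seen for Trp53inp2 (at least 5.52-fold), Rgs2 (−2.32 ± 0.11), the activation-induced gene Nr4a1 (−2.13 ± 0.11), the macrophage ficolin gene Fcna (−2.06 ± 0.10) and Irs2 (−2.06 ± 0.27). All 18 named genes called at day 7, Ifng (1.76 ± 0.13) and the regulatory cytokine gene Il10 (1.87 ± 0.15) among them, kept their calls under every alternative, while Tnf did not pass (0.09 ± 0.35, adjusted p = 0.838). By set Ifng rose by 2.73 ± 0.26 in intact females, 1.02 ± 0.26 in intact males, 1.65 in gdx females and 1.64 in gdx males. The sex difference of intact mice at day 7 (1.10 ± 0.26, adjusted p = 0.0557) and the sex by infection test for Ifng (adjusted p = 0.378) did not pass. Il10 rose by 2.14, 1.67, 1.68 and 1.98 in the same order of sets.

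All 24 cell cycle genes rose at day 7 (median 1.60, adjusted p = 0.0139 with an estimated correlation), with Rrm2 (2.94 ± 0.16) and Bub1 (at least 2.85) next to Cdk1. Of the plasma cell genes 13 of 14 rose (median 1.08), including Fkbp11 (at least 2.37), Creld2 (2.27 ± 0.12) and the transcription factor gene Xbp1 (1.37 ± 0.11). Irf4 fell (−0.64 ± 0.10). With an estimated correlation the list gave adjusted p = 0.0521. Of 15 B cell genes 13 fell, or 14 adjusted over the list alone (median −1.12, adjusted p = 0.0671 with an estimated correlation), such as Spib (−1.61 ± 0.10) and Cd72 (−1.21 ± 0.10). Of 15 T cell genes 12 fell, or 14 over the list alone (median −0.56, adjusted p = 0.272 with an estimated correlation), with Ccr7 at −1.78 ± 0.13, Bcl11b at −1.77 ± 0.29 and Cd8b1 at −0.92 ± 0.11. Immediate early and heat shock genes fell in 15 of 17 cases (median −1.06, adjusted p = 0.0159 with an estimated correlation): Atf3 by 2.01 ± 0.13, Hspa1b by 1.83 ± 0.23 and Junb by 1.76 ± 0.15. In the interferon-inducible list 17 of 22 genes were higher and 1 lower (median 0.80, adjusted p = 0.226 with an estimated correlation), and Iigp1 (2.94 ± 0.13) and Gbp2 (2.91 ± 0.17) stood above their day 3 changes. The regulatory and Th2 list had 7 higher and 3 lower of 13 (median 0.64, adjusted p = 0.0671 with an estimated correlation), led by Arg1 (at least 4.06), Lag3 (2.29 ± 0.19) and Pdcd1 (at least 1.69).

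In total 4716 genes (58.1% of those tested) passed at day 7, 1840 higher and 2876 lower, 412 and 236 of them by more than 2-fold. Of these 4362 had the same sign in all 4 sets. Intact females gave 1856 genes, intact males 2311, gdx females 2600 and gdx males 2658. In all 4 sets 631 rose and 504 fell, and 14 were called in opposite directions in different sets.

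At day 14 genes of red cell precursors rose most. Cldn13 rose by at least 5.40 (42.3-fold), Hemgn by 5.35 ± 0.27 (40.8-fold), the blood group glycoprotein gene Rhag by 4.93 ± 0.22 (30.4-fold), Tspo2 by at least 4.55, the anion exchanger gene Slc4a1 by 4.53 ± 0.26 and the erythroid transcription factor gene Klf1 by 4.38 ± 0.16 (20.8-fold). C1qtnf12 (4.42 ± 0.13) and Cdk1 (4.37 ± 0.28) were the others among the 8 largest rises. Lymphocyte genes fell: the T cell factor gene Bcl11b by 3.26 ± 0.29 (9.59-fold), the homing receptor gene Ccr7 by 2.97 ± 0.13 (7.83-fold), the natural killer receptor gene Klra8 by at least 2.90 and the B cell factor gene Ebf1 by 2.86 ± 0.24 (7.28-fold). Carns1 (at least 8.86-fold), Galnt6 (at least 7.39-fold), Coq8a (−2.77 ± 0.21) and Cd55 (−2.71 ± 0.12) fell to a similar extent. Of 21 named genes called at day 14, all but Eif2s3y and Xist kept the call under every alternative and without any single array. In the mean of the 4 sets Ifng was higher by 0.39 ± 0.13 (adjusted p = 0.0091), but by set it passed only in intact females (0.95), with 0.08 in intact males, 0.42 in gdx females and 0.09 in gdx males. Il10 was higher by 1.12 ± 0.15, while Tnf did not pass (−0.68 ± 0.35, adjusted p = 0.0853).

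All 21 erythroid genes (median 3.44, adjusted p = 0.0225 with an estimated correlation) and all 24 cell cycle genes (median 2.40, adjusted p = 0.0159 with an estimated correlation) rose at day 14, with Bub1b at 4.05 or more, Rrm2 at 3.82 ± 0.16 and Mki67 at 3.80 ± 0.18. Of the neutrophil genes 15 of 17 rose (median 2.25, adjusted p = 0.261 with an estimated correlation). Foremost were the granule genes Prtn3 (3.26 ± 0.32), Ctsg (at least 3.18), Camp (2.95 ± 0.26) and Elane (2.85 ± 0.25), while the receptor genes Csf3r (−0.99 ± 0.15) and Cxcr2 (−0.94 ± 0.32) fell. Of 15 B cell genes 14 fell (median −1.95, adjusted p = 0.0422 with an estimated correlation), among them Blk (−2.30 ± 0.09) and Cd79a (−2.23 ± 0.17). All 15 T cell genes fell (median −1.29, adjusted p = 0.0978 with an estimated correlation), with Il7r at −2.64 ± 0.11 and Lef1 at −2.44 ± 0.15. All 9 MHC class II genes fell (median −1.02, adjusted p = 0.103 with an estimated correlation), such as H2-DMb2 (−1.45 ± 0.11) and H2-Ab1 (−1.31 ± 0.13). Plasma cell genes remained higher in 12 of 14 cases, with Irf4 lower (median 0.90, adjusted p = 0.223 with an estimated correlation). The interferon-inducible list was mixed, with 12 higher and 3 lower of 22 (median 0.42, adjusted p = 0.634 with an estimated correlation): Rsad2 rose by 2.53 ± 0.14 while Ifit3 fell by 0.70.

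In total 5404 genes (66.5%) passed at day 14, 2207 higher and 3197 lower, with 679 and 691 beyond 2-fold, and 5154 had the same sign in all 4 sets. Intact females gave 3530, intact males 3629, gdx females 3156 and gdx males 3669. In all 4 sets 1055 rose and 1228 fell, and 8 were called in opposite directions in different sets.

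The next question was whether the sexes differed, and whether a difference needed the gonads. In intact mice as the mean of 4 days, Xist, the gene of X inactivation, was higher in females by 4.81 ± 0.14 (28.1-fold), as were the X-linked Kdm6a (1.27 ± 0.12) and Eif2s3x (0.48 ± 0.06). The Y-linked Eif2s3y was at least 8.41-fold lower in females, with Kdm5d (−1.01 ± 0.14) and Uty (−1.37 ± 0.20). Outside these lists only Erdr1 (1.59 ± 0.22, 3.01-fold, adjusted p = 1.08e-05) and the chemokine gene Cxcl2 (0.75 ± 0.16, adjusted p = 0.0347) passed, and Cxcl2 lost its call under 3 alternatives. The total was 8 genes with limma, and 796 at unadjusted p under 0.05.

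**Figure D3:**
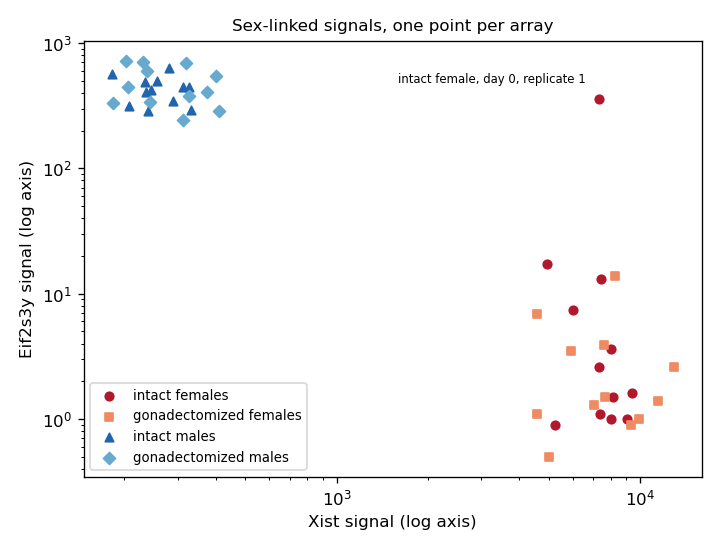
Signals of Xist and Eif2s3y on the 48 arrays. The intact female day 0 replicate 1 array had a Xist signal of 7332 and an Eif2s3y signal of 355, while the other female arrays reached at most 17.3 for Eif2s3y.

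At day 0 the intact sexes differed in 5 genes: Xist, Eif2s3y, Erdr1 (3.05 ± 0.44), the acute phase gene Hp (1.88 ± 0.37, adjusted p = 0.0154) and Klf1 (1.67 ± 0.32, adjusted p = 0.0103). One of the 3 female arrays of this comparison, replicate 1, had a signal of the Y-linked Eif2s3y in the range of males (355, males 244 to 719) beside a female signal of Xist. Its Kdm5d (185) and Uty (124) signals also lay in the male range, but other female arrays reached 208 and 122, just below its Uty signal, so that only Eif2s3y set the array far apart. Its neutrophil genes averaged 11.9 on the log2 scale against 10.1 and 10.2 in the group's other arrays, and its erythroid genes 9.62 against 8.13 and 8.18. Without this array, chosen after the data were seen, 3 genes were left and Hp and Klf1 were not among them. Without intact female replicate 2 the count was 48, without intact female replicate 3 it was 26, and without intact male replicate 3 it was 16. With the replicate number as a block it was 17. No neutrophil gene passed at day 0 over all genes, while 13 of 17 were higher adjusted over the list alone (median 1.12, adjusted p = 0.00371 with an estimated correlation). The median was 0.75 without the array. Cell cycle genes had a median of 0.46 with 0 called and 7 over the list alone (adjusted p = 0.0396 with an estimated correlation), a call lost without the array.

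At day 3 the intact sexes differed in 3 genes, Xist, Kdm6a and Eif2s3y. At day 7 they differed in 16, 7 higher and 9 lower in females. Gdap10 (0.95 ± 0.18), the splicing factor gene Rbm39 (0.82 ± 0.19, adjusted p = 0.0493, with no other probe set passing), Cd274 (0.77 ± 0.16) and the T cell adaptor gene Lat (0.76 ± 0.16) were higher in females. Cideb (−2.04 ± 0.39, 4.10-fold), Pcp4 (at least 3.59-fold), the protease inhibitor gene Slpi (−1.53 ± 0.30) and the antibody light chain gene Igkv15-103 (−1.22 ± 0.24) were lower, as was Xbp1 (−1.04 ± 0.22, adjusted p = 0.0232). The count was 61 without intact male day 7 replicate 1 and 3 without intact female or intact male day 7 replicate 3, and it was 4 when only the 6 arrays compared were fitted, where Cideb, Cd274, Lat and the other autosomal genes named first lost their calls. With the replicate number as a block the count was 33. By list the regulatory and Th2 genes had a median of 0.33 with Cd274 called and 2 over the list alone, and glucocorticoid-induced genes one of 0.54 with 0 called and 2 over the list alone (adjusted p = 0.0134 with an estimated correlation for each). Plasma cell genes had a median of −0.53 with 1 called and 5 over the list alone, at adjusted p = 0.0544 with an estimated correlation. At day 14 the intact sexes differed in 3 genes: Xist, Eif2s3y and the coactivator gene Mrtfa (−0.80 ± 0.16, adjusted p = 0.024), with 1 higher and 2 lower, or 1 each way after quantile normalization, when Mrtfa lost its call. Endoplasmic reticulum chaperone genes had a median of 0.41 at day 14 with 0 called and 4 over the list alone (adjusted p = 2.17e-04 with an estimated correlation), where Pdia4 (1.39 ± 0.38, adjusted p = 0.561) and Hsp90b1 (0.61 ± 0.26) did not pass.

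In gdx mice neutrophil genes separated the sexes. As the mean of 4 days Lrg1 was higher in females by at least 2.07 (4.19-fold) and Chil3, which encodes a chitinase-like protein, by 2.06 ± 0.21 (4.18-fold). The granule genes followed, Prtn3 by 1.94 ± 0.32 and Lcn2 by 1.92 ± 0.23. Camp (1.87 ± 0.26) and Ctsg (at least 1.68) came next. The largest differences the other way were smaller: Dapp1 (−0.63 ± 0.17), Agtpbp1 (−0.59 ± 0.15), Ubr2 (−0.58 ± 0.14), Gtf3c4 (−0.57 ± 0.13), Zfp90 (−0.50 ± 0.14) and Pars2 (−0.50 ± 0.13). Dapp1, Zfp90 and Pars2 each lost the call under 1 alternative, and the other probe set of Dapp1 gave 0.27 (adjusted p = 0.209). Of the neutrophil list 15 of 17 were higher (median 1.21, adjusted p = 2.62e-04 with an estimated correlation). Of the immediate early and heat shock list 10 of 17 were higher (median 0.33, adjusted p = 2.17e-04 with an estimated correlation), such as Atf3 (1.21 ± 0.13), Dusp1 (0.74) and Jun (0.64). Smaller shifts were found in glucocorticoid-induced genes (5 of 11 higher, median 0.23, adjusted p = 0.00169 with an estimated correlation, Il1r2 0.91 and Tsc22d3 0.48). The same held for Toll-like receptor genes (3 of 13, or 4 over the list alone, 0.16, adjusted p = 0.0371 with an estimated correlation, Cxcl2 1.37 ± 0.16) and endoplasmic reticulum chaperones (3 of 16, 0.19, adjusted p = 0.0293 with an estimated correlation, Dnajb9 0.59). Erythroid genes (4 higher, 12 over the list alone, median 0.41, Slc4a1 1.10 ± 0.26) lost their list call with an estimated correlation (adjusted p = 0.109). Among sex-linked genes Xist was 26.9-fold higher in females and Eif2s3y at least 10.8-fold lower. The total was 198 genes, 160 higher and 38 lower, with 28 and 2 beyond 2-fold.

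The difference between gdx females and gdx males was largest before infection. At day 0 it held 193 genes (167 higher, 26 lower), with Prtn3 at 4.25 or more (at least 19.0-fold), Lcn2 at 4.09 ± 0.45 (17.1-fold), Chil3 at 4.03 ± 0.43 and Camp at 3.93 ± 0.52. In the other direction were Zdhhc12 (−1.99 ± 0.54), Foxh1 (−1.90 ± 0.39), Ilf2 (−1.55 ± 0.38) and Tbx6 (−0.97 ± 0.23). The other probe set of Ilf2 gave 0.34 (adjusted p = 0.857), so that the lower value was not seen on it. The granule gene S100a9 had a mean signal of 41340 in gdx females, 6070 in gdx males, 27020 in intact females and 14230 in intact males. The count at day 0 was 113 without gdx female replicate 2 and 120 without gdx female replicate 3. At day 3 there were 15 genes, among them Camp (2.58 ± 0.52), Chil3 (2.53 ± 0.43), Lcn2 (2.32 ± 0.45) and Ngp (2.29 ± 0.43), which lost their calls with only the arrays compared, and 2 genes without gdx male replicate 2 or gdx female replicate 3. At day 7 only Xist and Eif2s3y passed, and 6 genes without gdx male replicate 1. At day 14 there were 12 genes (9 higher and 3 lower, or 3 and 2 after quantile normalization). The red cell genes Xpo7 (1.61 ± 0.30) and Bpgm (1.57 ± 0.33), Tbcel (1.15 ± 0.25) and Ccr7 (1.13 ± 0.26) were higher and Mrpl49 (−0.71 ± 0.15) lower, and 2 genes were left without gdx female replicate 3. Bpgm, Tbcel, Ccr7 and Mrpl49 lost their calls after quantile normalization, and Ccr7 also with the replicate number as a block. The median of the neutrophil list was 2.77 at day 0 (16 of 17 higher), 1.47 at day 3 (6, or 13 over the list alone), 0.46 at day 7 and 0.31 at day 14 (0 called on the later days).

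Gonadectomy itself was then compared within each sex over the 4 days. In females the neutrophil genes Camp (1.37 ± 0.26, adjusted p = 0.0259), Ltf (1.11 ± 0.23), Lcn2 (1.10 ± 0.23), Ngp (1.09 ± 0.21) and Chil3 (0.98 ± 0.21) and the fibronectin gene Fn1 (0.67 ± 0.13) were higher after gonadectomy. The total was 9 genes, all higher, with 452 at unadjusted p under 0.05. The neutrophil list had 6 of 17 higher, or 14 over the list alone (median 0.67, adjusted p = 0.00989 with an estimated correlation). The count was 0 under eBayes without the intensity trend, without the filter on dim probe sets and with only the arrays compared, and it ranged from 0 to 40 as single arrays were left out. Without the array with signals of both sexes it was 40 (38 higher), with 13 neutrophil genes higher and a median of 0.91. In males 13 genes passed (736 at unadjusted p under 0.05), all with small changes. Zeb2 (0.63 ± 0.14), the kynurenine pathway gene Kmo (0.46 ± 0.09), Ero1b (0.39 ± 0.07), Bach2 (0.38 ± 0.08), Smarcc1 (0.37 ± 0.08) and the B cell receptor gene Cd79b (0.34 ± 0.07) were higher after gonadectomy. Atf3 (−0.61 ± 0.13) and the lectin gene Clec7a (−0.40 ± 0.08) were lower. The other probe sets of Ero1b and Smarcc1 did not pass, and that of Smarcc1 had the opposite sign (−0.06). Each of these 8 genes lost its call under some alternative, and the count ranged from 0 to 24 as single arrays were left out. It was 31 with the replicate number as a block and 22 after quantile normalization. Natural killer genes had a median of −0.23 in males with 0 called and 1 over the list alone (adjusted p = 0.0388 with an estimated correlation).

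The interaction of sex and gonadectomy asked whether the sex difference itself depended on the gonads. It was called for 5 genes, with 625 at unadjusted p under 0.05, and in each the female minus male difference was higher in gdx mice. For Chil3 it was 0.40 ± 0.21 in intact mice and 2.06 in gdx mice (interaction −1.66 ± 0.30, adjusted p = 0.0103), and for the haem synthesis gene Alas2 −0.48 and 0.78 (−1.26 ± 0.26). The stress-response gene Atf3 had 0.22 and 1.21 (−0.99 ± 0.18), the GTPase gene Rhob −0.11 and 0.83 (−0.94 ± 0.18), and S100a9 0.30 and 1.19 (−0.89 ± 0.19, adjusted p = 0.0469). S100a9 lost its call with the replicate number as a block, after quantile normalization and without the intensity trend, and Alas2 without the trend. The count was 0 without the filter on dim probe sets and 34 (28 lower, all 5 genes included) without the array with signals of both sexes, where 11 neutrophil genes passed and the list median moved from −0.89 to −1.09. It was 12 without intact male day 0 replicate 1 and 9 without gdx male day 3 replicate 1.

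Whether the response to infection differed by sex was tested over the 3 infected days. In intact mice 0 genes passed the moderated F test of limma, with 393 at unadjusted p under 0.05, and the smallest adjusted p was 0.0954 for Klf1. The count was 1 after quantile normalization and 5 without intact female day 7 replicate 2. Of 66 list tests 28 were called, and endoplasmic reticulum chaperones were the only list left with an estimated correlation (day 14, median 0.41, adjusted p = 0.00374), with 0 genes called and 3 over the list alone. In gdx mice 26 genes passed, 7 of them in the neutrophil list, and for 24 the infection change was lower in females on all 3 days. The differences between female and male changes at days 3, 7 and 14 were −1.17, −2.45 and −2.70 for S100a9 (adjusted p = 1.33e-04), −2.88, −3.30 and −3.60 for Hp and −1.29, −2.32 and −2.61 for S100a8. Chil3, Ifitm2, Cxcl2, Gsr, Lcn2, Clec7a and Litaf completed the 10 smallest adjusted p. Of the 26 genes 25 also differed between gdx females and gdx males at day 0. The differences at the 3 days share the same day 0 arrays, so their common sign is not independent. Relabelled splits did not exclude chance for the count of 26, as 5 of 100 had as many calls. The sexes were relabelled separately within each day, which can turn a steady sex difference into an interaction. These splits thus do not decide the question. The median change of the neutrophil list at day 14 was 0.84 in gdx females, 3.12 in gdx males, 1.15 in intact females and 2.97 in intact males. In intact females the day 0 side held the array with signals of both sexes, with a list mean of 11.9 against 10.1 and 10.2. The count of genes in gdx mice was 12 without gdx female day 0 replicate 2. It was 40 without the array with signals of both sexes. That array is outside the gdx comparison and enters it only through the variances of the shared fit.

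Gonadectomy by infection gave 0 genes in females with limma, 296 at unadjusted p under 0.05, and 1 without intact female day 0 replicate 2. In males it gave 2 genes at adjusted p = 0.0387, the aminopeptidase gene Lap3 (differences 1.54, 1.39 and 1.34 at days 3, 7 and 14) and Cr2 (0.27, −0.15 and 1.21), and between 0 and 9 as single arrays were left out. Lap3 and Cr2 both lost their calls without the intensity trend, without the dim filter and with only the arrays compared.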

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

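The criteria of all tests in this part were set after the results were seen, except those for RNA quality and a handling response, which were set before. Differences between groups were what drew attention to 4 results. Sex by gonadectomy differed in 5 genes (Chil3, Alas2, Atf3, Rhob and S100a9) and sex by infection in gdx mice in 26, with S100a9, Hp and S100a8 first. Gonadectomy by infection in males differed in 2 genes, Lap3 and Cr2. For these 2 and for the 26 genes of sex by infection, relabelled splits did not exclude chance. Labels were drawn separately within each day, so a steady difference could turn into an interaction, and the splits do not test it. The endoplasmic reticulum chaperones differed between intact females and males in their day 14 change by a median of 0.407. That median was 0.402 without the array with signals of both sexes, and 0 of its genes passed singly.

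The first pattern weighed is the male signals in intact female day 0 replicate 1, where the Y-linked Eif2s3y reached 49.4% of the highest male signal. A male array under a female label was excluded by its Xist signal of 7332, against at most 409 in males. RNA of infected day 14 mice in the pool was left open: neutrophil genes would need a share of 91.6%, erythroid genes 13.7% and cell cycle genes 18.1%, but an uninfected gdx female array reached a neutrophil mean above its 11.9, so that neutrophil level does not measure day 14 RNA. Male RNA mixed into the pool was not decided either, because only 1 tested Y-linked gene, Eif2s3y, separates the sexes. Xist was not used to decide it. The signal lay near the median of the other female arrays (7592), which ranged from 4565 to 12920, and the group's other arrays had 7424 and 9410. Whether such a signal leaves room for the male share that Eif2s3y would need was not tested. Eif2s3y reached 76.3% of the male day 0 median, against a signal of at most 17.3 in the other female arrays.

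The second pattern is the higher neutrophil genes of gdx females. All 5 of the brightest neutrophil genes were higher (S100a9 1.19, S100a8 1.21, Ngp 1.66, Camp 1.87, Ltf 1.59), which restates the difference and does not test whether the pools held more neutrophil RNA, so that explanation was left open. For RNA quality the list median was 1.24 with the 3 prime to 5 prime ratios of Actb and Gapdh in the fit and 1.21 without. These ratios thus did not account for the difference. Their slopes rest on the scatter between the 3 arrays of a group, so a quality difference between groups was not excluded. With the immediate early mean in the fit the median was 1.19 (quartiles 0.736 to 1.87), against quartiles of 0.778 to 1.68 before. The slope of that mean also rests on the scatter within groups, and the immediate early list itself was higher in gdx females. A handling response that differed between groups was therefore not excluded. The calls did fall, from 15 to 8 neutrophil genes and from 198 to 29 genes in all, as the median standard error of the neutrophil genes went from 0.214 to 0.341 while their differences stayed.

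The third pattern is the fall of lymphocyte genes beside the rise of erythroid and neutrophil genes at day 14. Array scaling was excluded, since 7817 genes in no list had a median change of −0.13, against −1.95 for B cell and −1.29 for T cell genes. A lower share of lymphocytes alone was excluded, since macrophage genes had a median of −0.13 and erythroid genes one of 3.44. Even dilution of all other cells as the only change was excluded, since the lower quartile of macrophage genes (−0.52) lay above the upper quartile of B cell genes (−1.45). This exclusion and that of a lower lymphocyte share assume unchanged expression within the cell types, which was not tested. Separate losses and gains of cell types, or of expression within them, are likely but were not told apart.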

How the results depend on the processing

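Of 113 gene list calls and 176 named gene calls, 0 reversed direction under any setting. The infection means kept their counts within 1.5 times under every setting but that with every probe set as its own feature, and leaving out single arrays of the groups compared gave 157 to 208 genes at day 3, 4537 to 4841 at day 7 and 5292 to 5417 at day 14. Counts that moved by more than 1.5 times are given by setting; unless stated, the cause was not tested.

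After quantile normalization day 3 in gdx females gave 40 genes, sex in intact mice at day 0 22, sex in gdx mice at day 14 5, gonadectomy in males 22 and sex by infection in intact mice 1. With the floor at the 5th percentile sex in intact mice gave 15 at day 0 and 5 at day 3, and gonadectomy by infection in males 4. With no filter on dim probe sets, where more genes share the adjustment, day 3 in intact females gave 11, sex in intact mice at day 3 5, gonadectomy 0 in females and 2 in males, sex by gonadectomy 0, sex by infection in gdx mice 15, and gonadectomy by infection 1 in females and 0 in males. With every probe set as its own feature the 13467 features made larger counts possible: infection gave 7727 at day 7 and 8990 at day 14. By set it gave 3639 in intact males, 3962 in gdx females and 4174 in gdx males at day 7, and 5618, 5904, 4985 and 5910 in intact females, intact males, gdx females and gdx males at day 14. Sex in intact mice gave 18 as the mean and 15, 8, 34 and 8 at days 0, 3, 7 and 14, sex in gdx mice 7 at day 7 and 23 at day 14, gonadectomy in males 0 and gonadectomy by infection in males 0.

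With the replicate number as a block, sex in intact mice gave 17 at day 0 and 33 at day 7, and gonadectomy in males 31. With only the arrays of the groups compared, which leaves fewer degrees of freedom, day 3 gave 0 in intact females, 3 in intact males and 21 in gdx males. Sex in intact mice gave 1 at day 0 and 4 at day 7, sex in gdx mice 109, 2 and 5 at days 0, 3 and 14, gonadectomy 0 in both sexes, sex by infection in gdx mice 41 and gonadectomy by infection in males 1. With eBayes without the intensity trend sex in gdx mice at day 14 gave 5, gonadectomy 0 in both sexes, sex by gonadectomy 3 and gonadectomy by infection in males 0. With the doubtful array left out, a setting chosen after the data were seen, day 3 in intact females gave 7, sex in intact mice at day 0 3, gonadectomy in females 40, sex by gonadectomy 34 and sex by infection in gdx mice 40. List calls with an estimated correlation numbered 7 of 29 for infection, 15 of 40 for sex, 3 of 16 for gonadectomy and 1 of 28 for sex by infection, and with fry 19 for sex, 3 for gonadectomy and 1 for sex by infection.

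Leaving out single arrays, here only those of the groups compared, gave for day 3 a range of 3 to 45 genes in intact females, 9 to 48 in intact males, 10 to 28 in gdx females and 18 to 27 in gdx males. Sex in intact mice ranged from 3 to 48 at day 0 and 3 to 61 at day 7, and in gdx mice from 113 to 218 at day 0, 2 to 18 at day 3, 2 to 6 at day 7 and 2 to 15 at day 14. Gonadectomy ranged from 0 to 40 in females and 0 to 24 in males, sex by gonadectomy from 3 to 34, sex by infection from 0 to 5 in intact and 12 to 33 in gdx mice, and gonadectomy by infection from 0 to 1 in females and 0 to 9 in males. At least 1 such fit ended 39 of the list calls and 61 of the named gene calls. Among the other settings, calls ended for 7 lists and 9 genes after quantile normalization, 0 and 6 with the lower floor, 6 and 39 with no dim filter, 0 and 2 with the block, 2 and 52 with only the arrays compared, and 17 and 9 with the doubtful array left out, and for 26 genes without the trend. Signal over background limited the genes near the floor of 41.4, where a fold is a lower bound, and Il12b and Esr1 were below the filter.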

Other observations

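Red cell precursor genes were already rising at day 7, with 14 of 21 erythroid genes higher and 1 lower (median 0.86, adjusted p = 0.215 with an estimated correlation). Rhag rose by 3.02 ± 0.22, the carbonic anhydrase gene Car1 by 2.68 ± 0.18, Hemgn by 2.68 ± 0.27 and Ermap by 2.27 ± 0.16. Endoplasmic reticulum chaperones rose along with the plasma cell genes, 11 higher and 3 lower of 16 (median 0.56, adjusted p = 0.12 with an estimated correlation), with Manf at 1.60 ± 0.10, Sdf2l1 at 1.32 ± 0.14 and Dnajb9 at −1.23 ± 0.10. The interferon-gamma axis had 8 higher and 4 lower of 17 (median 0.18, adjusted p = 0.272 with an estimated correlation), and its call was lost after quantile normalization. In the mean of the 4 sets neutrophil genes had 9 lower and 3 higher of 17 (median −0.56), such as Ltf (−1.39 ± 0.23), Csf3r (−1.37 ± 0.15) and Camp (−1.35 ± 0.26) against Ctsg (at least 1.37). The list itself was not called, and its medians by set were −1.01 in intact females, −1.23 in gdx females, −0.41 in intact males and 0.81 in gdx males. The intact female value depends on the day 0 array with signals of both sexes, whose list mean was 11.9 against 10.1 and 10.2 in its group.

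Several lists held genes moving both ways at day 7 and were not called. Of the natural killer genes 4 were higher and 7 lower, or 5 and 8 over the list alone, with a median of −0.34, a mean of 0.06 and a downward test direction. Gzmb and Gzmk (2.28 ± 0.11) rose while the receptor gene Ncr1 (−1.57 ± 0.13) and Xcl1 (−1.54 ± 0.16) fell. Of the macrophage genes 8 were higher and 9 lower, with a median of −0.23 but a mean of 0.06 and an upward test. Fcgr4 (1.65 ± 0.10) and the haem-degrading Hmox1 (1.57 ± 0.11) rose and Mrc1 (−1.16 ± 0.11) fell. Dendritic genes had 1 higher and 3 lower (Cd209a −1.52 ± 0.16) and MHC class II genes 0 and 5 (median −0.28, H2-DMb2 −0.57). There were 2 and 5 for Toll-like receptor genes (Il1b −1.48 ± 0.12, Myd88 0.54) and 3 and 6 for glucocorticoid-induced genes (median −0.49, Per1 −1.37, Fkbp5 1.20). Smaller lists gave 2 higher and 3 lower for megakaryocyte genes (Ppbp 0.68, Clec1b −0.44), 2 and 4 for sex steroid genes (Hsd17b11 −0.66, Pgrmc1 0.49). They gave 0 and 1 for stroma (Pecam1 −0.38), 1 and 3 for X-linked genes (Kdm6a −0.56) and 0 for exocrine pancreas genes. Of the 3 tested germinal centre genes Basp1 rose (0.29 ± 0.08) and Lmo2 fell (−0.26 ± 0.06).

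At day 14 glucocorticoid-induced genes fell in 6 of 11 cases with 0 higher (median −0.76, adjusted p = 0.172 with an estimated correlation), led by Tsc22d3 (−2.55 ± 0.11) and Sgk1 (−1.85). Immediate early and heat shock genes had 14 lower and 2 higher of 17 (median −1.03, adjusted p = 0.0671 with an estimated correlation), with Junb at −2.07 and Nr4a1 at −1.81. The other day 14 lists were not called. Natural killer genes had 3 higher and 10 lower (median −0.43, Gzmb 3.45 ± 0.12, Ncr1 −1.43), macrophage genes 5 and 8 (median −0.13, Vcam1 −1.42, Fcgr4 1.14) and dendritic genes 0 and 5, or 1 and 5 over the list alone (Cd209a −1.59, Cd83 −1.16). The interferon-gamma axis had 4 and 7 (Cxcl9 2.38 ± 0.27, Il18r1 −2.17 ± 0.18). Regulatory and Th2 genes had 3 higher and 6 lower (Pdcd1 at least 1.54, Il10ra −1.75), endoplasmic reticulum chaperones 11 and 4 (median 0.48, Sdf2l1 1.21, Dnajb9 −1.26) and Toll-like receptor genes 0 and 8 (Tlr1 −1.49). Sex steroid genes had 1 and 4 (Ncoa3 −0.79), megakaryocyte genes 2 and 0, stroma 0 and 1 (Pecam1 −1.18), and X-linked genes 1 and 4. Exocrine pancreas genes had 1 higher (Cela1 1.06) and 1 lower (Rnase1 −0.47), with a median of −0.17 and a mean of 0.04. The germinal centre gene Lmo2 rose (0.63 ± 0.06). Among sex-linked genes Xist (−0.36 ± 0.14, adjusted p = 0.0216), Uty (−0.50) and Kdm5d (−0.44) were lower at day 14 than at day 0, and Xist lost its call without gdx male day 14 replicate 1. The call of Eif2s3y, which was at the floor in most female arrays, was lost without the array with signals of both sexes.

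At day 3 small shifts of whole lists were called at the preset correlation and lost with an estimated one: cell cycle (median 0.17, 0 genes called and 1 over the list alone, adjusted p = 0.31), T cell (−0.10, 0 called, adjusted p = 0.611), natural killer (0.10, Gzmb and Xcl1 called and 3 over the list alone, adjusted p = 0.2), neutrophil (−0.42, 0 called and 2 lower over the list alone, adjusted p = 0.206), MHC class II (0.12, adjusted p = 0.385) and glucocorticoid-induced genes (−0.17, Il1r2 −0.61 ± 0.16 and Cxcr4 −0.54 ± 0.12 lower, adjusted p = 0.0671). Lists not called at day 3 included macrophage genes (2 higher and 4 lower, Fcgr1 0.56, Mrc1 −0.48) and X-linked genes (1 lower, Kdm6a −0.47). Median and mean had opposite signs there for erythroid (0.02 and −0.03), dendritic (0.02 and −0.02), endoplasmic reticulum chaperone (0.02 and −0.01) and X-linked genes (0.01 and −0.08). The neutrophil list had day 3 medians of −1.05 in intact females, −0.998 in gdx females, 0.15 in intact males and 0.29 in gdx males. Day 0 list means of intact females were 11.9 in the array with signals of both sexes, and 10.1 and 10.2 in the others. The sex by infection call of the neutrophil list in intact mice at day 3 was lost with an estimated correlation (adjusted p = 0.0786) and with fry. The list difference was −1.05 there, and −0.73 without the array with signals of both sexes, which is 1 of the day 0 arrays of intact females. At day 3 the intact sexes also had list calls that an estimated correlation ended, for the interferon-gamma axis (−0.17, 1 lower over the list alone, adjusted p = 0.297), interferon-inducible (−0.16, adjusted p = 0.7), cell cycle (0.11, adjusted p = 0.67) and glucocorticoid-induced genes (0.22, adjusted p = 0.113).

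Sex and gonadectomy gave further list calls that were lost with an estimated correlation. In intact mice at day 0 these were erythroid (median 0.40, Klf1 called and 7 over the list alone, adjusted p = 0.108), macrophage (0.27, 1 over the list alone, adjusted p = 0.106), natural killer (−0.18, adjusted p = 0.35) and immediate early genes (−0.07, 1 higher and 2 lower over the list alone, adjusted p = 0.36). At day 7 they were interferon-inducible (0.43, adjusted p = 0.264), the interferon-gamma axis (0.19, 1 over the list alone, adjusted p = 0.35), cell cycle (−0.29, adjusted p = 0.545), erythroid (−0.43, adjusted p = 0.386), T cell (0.36, adjusted p = 0.245), MHC class II (0.22, 1 over the list alone, adjusted p = 0.27) and immediate early genes (0.24, 5 over the list alone, adjusted p = 0.0939). At day 14 they were interferon-inducible (0.17, adjusted p = 0.544), plasma cell (0.31, adjusted p = 0.109) and glucocorticoid-induced genes (0.25, adjusted p = 0.174). X-linked genes were called with an estimated correlation at day 0 (0.49, 1 called and 3 over the list alone, adjusted p = 2.58e-08) and day 3 (2 called and 3 over the list alone, adjusted p = 2.68e-09). The sex difference of this list was not confined to these days. Its genes Xist, Kdm6a and Eif2s3x also passed at day 7 and Xist at day 14. In gdx mice over the 4 days Xist, Kdm6a, Kdm5c and Eif2s3x passed. In gdx mice over the 4 days the lost calls were regulatory (0.12, Ctla4 0.63 and Cd274 0.40 higher, 3 over the list alone, adjusted p = 0.109), cell cycle (0.08, 1 over the list alone, adjusted p = 0.454), B cell (−0.14, Cxcr5 −0.41 ± 0.09 lower, 5 over the list alone, adjusted p = 0.27), natural killer (0.10, adjusted p = 0.383) and macrophage genes (0.24, Lyz2 0.71 and Cd14 0.48 higher, 6 over the list alone, adjusted p = 0.0852).

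After gonadectomy in females the immediate early list was called with an estimated correlation (0.17, 0 genes called and 6 over the list alone, adjusted p = 0.00483). Calls lost with it were interferon-inducible (−0.11, adjusted p = 0.671), cell cycle (0.09, adjusted p = 0.671), erythroid (0.32, 8 over the list alone, adjusted p = 0.166), plasma cell (0.11, adjusted p = 0.418), T cell (−0.16, 1 over the list alone, adjusted p = 0.213) and endoplasmic reticulum chaperone genes (0.07, adjusted p = 0.213). In males they were B cell (0.14, Cd79b called and 3 over the list alone, adjusted p = 0.194), T cell (−0.15, 3 over the list alone, adjusted p = 0.294), macrophage (−0.11, 2 over the list alone, adjusted p = 0.418), neutrophil (−0.17, 2 over the list alone, adjusted p = 0.671), megakaryocyte (−0.18, 1 over the list alone, adjusted p = 0.176), immediate early (−0.12, Atf3 called and 2 over the list alone, adjusted p = 0.294) and Toll-like receptor genes (−0.12, 3 over the list alone, adjusted p = 0.176). The fixed cytokine and receptor genes Il12b and Esr1 were too dim to test, with Esr1 at a median signal of 30.2.

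The tests by splits were set after the results were seen. Relabelled arrays gave the following splits, named by comparison with the real count and then the highest of the other splits. With 3 arrays against 3 there were only 10 splits, too few to exclude chance. For infection these were 18 and 0 in intact females, 30 and 1 in intact males, 21 and 1 in gdx females, and 32 and 3 in gdx males at day 3. They were 1856 and 45, 2311 and 2, 2600 and 0, and 2658 and 2 at day 7, and 3530 and 37, 3629 and 7, 3156 and 0, and 3669 and 2 at day 14. For sex in intact mice they were 5 and 1 at day 0, 3 and 23 at day 3, 16 and 1 at day 7, and 3 and 8 at day 14, and in gdx mice 193 and 3, 15 and 1, 2 and 0, and 12 and 2. The real split was the only 1 with as many calls except for intact mice at days 3 and 14, where 2 splits had as many. The split with 23 genes at day 3 points to a structure of those arrays: 10 of the 23 were interferon-inducible genes, and it set the arrays with list means of 10.9 to 11.4 (intact female replicate 3, intact male replicates 1 and 2) against those with 10.2 to 10.3.

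With 100 drawn splits chance was excluded for infection at day 3 (205, highest other 4), day 7 (4716 and 3777) and day 14 (5404 and 4934). It was also excluded for sex in gdx mice (198 and 45), each of these with 1 split having as many calls. Gonadectomy in males (13 and 4) likewise had 1 such split. Its count was 0 under some alternatives and the shares were not adjusted over comparisons, so chance was not firmly excluded there. For sex in intact mice (8 and 9, with 2 splits) chance was excluded for the count, but 6 of the 8 genes were sex-linked, so that nothing follows for Erdr1 and Cxcl2. For the list calls of sex (40 and 36, with 1 split) chance was excluded for the count. It includes calls of the X-linked list, which relabelling the sexes removes, so nothing follows for the other lists. For gonadectomy in females (9 and 13, with 3 splits) and the list calls of gonadectomy (16 and 18, with 4 splits) at least 1 other split exceeded the real count. The shares were not adjusted over comparisons, and the count in females was 0 under some alternatives, so chance was not firmly excluded. For sex by gonadectomy (5 and 12, with 3 splits) the sexes were relabelled within intact and gdx mice. That removes any sex difference, so it does not test the interaction. Chance was not excluded for the list calls of infection (29 and 37, with 5 splits). Nor was it for sex by infection in gdx mice (26 and 131, with 5 splits) or gonadectomy by infection in males (2 and 8, with 9 splits). The same held for the list calls of sex by infection (28 and 32, with 9 splits). For these interactions the labels were drawn separately within each day. A steady difference between groups can then turn into an interaction, so these splits do not test it. For sex by infection in intact mice (0, highest other 33) and gonadectomy by infection in females (0 and 26) the real count of 0 is reached by all 100 splits by construction, so the splits test nothing there. The split with 131 genes can come from a steady sex difference that was relabelled differently by day. Whether it also reflects a structure of the samples was not tested.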
